A study of Mus musculus with 6 samples.

How the data were processed

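Per the labels' protocols, total RNA was purified with a Qiagen RNeasy Plus column kit and libraries were made with the TruSeq RNA kit, version v2, which does not mark strand. Per the labels, the 6 libraries came from basal cell carcinoma cells of mouse ear epidermis, 6 weeks after tamoxifen given at 4 weeks of age, 3 from SmoM2 mice with wild-type Yap and 3 from SmoM2 mice with floxed Yap. The growth protocol speaks of cells taken 6 or 9 weeks after tamoxifen, and the stage label of each of these samples gives 6 weeks. The labels do not say that each library came from a separate animal or from a pool, so p-values measure the spread between these libraries. Per the submitters' processing notes, STAR 2.5 and DESeq2 1.18.1 were used with the mouse build mm10 (GRCm38). The counting tool, the gene annotation, the strand setting and any filter were not given in the sources used here. Reads from overlapping or antisense genes and from near-identical gene copies could not be told apart. The 2 Hspa1 genes of the stress list are such copies.

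The authors deposited 1 table of 23337 genes by 6 libraries, a signal made of read counts divided by one size factor per library. This was tested on the values: in each library 100% of values were whole multiples of one step (tolerance 0.001 reads), and the steps equalled median-of-ratios size factors computed from the recovered reads (1.19, 1.04 and 0.769 in wild type, 1.12, 1.21 and 0.791 in knockout, libraries 1 to 3). Each column was matched to its sample by the code in its name. No read was recorded in any library for 5122 genes. Recovered reads per library ran from 15405490 to 25260431. A count of 3 reads, the upper limit that 0 reads allow, equals 2.47 to 3.90 normalized counts depending on the library, and covers counting error only.

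Genes with a mean of at least 10 normalized counts over the 6 libraries were tested (13671 genes). The test fixed before the data were examined was limma 3.58.1 (R 4.3.3) with a mean-variance trend and robust prior on log2(normalized count + 1), knockout against wild type, 3 against 3, no covariate, two-sided, with Benjamini-Hochberg adjustment at 0.05. Limma, edgeR and DESeq2 without a term called 0, 0 and 67 genes. Log2 differences are on the log2(normalized count + 1) scale, knockout minus wild type, which understates changes of low genes. Unless named otherwise they come from limma. As an alternative fixed beforehand, the recovered reads were tested with edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0. The smallest p an exact permutation test of 3 against 3 allows is 0.1, so none was run on single genes.

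The replicate numbers 1 to 3 are shared by the groups. Deviations from the group means correlated across genes by 0.333, 0.327 and 0.694 between libraries with the same number, above 0.1 for each pair, so by the rule fixed for this check the numbers were taken to pair the libraries. Knockout library 1 correlated more with wild-type library 2 (0.505), and knockout library 2 with wild-type library 1 also passed (0.26). Combinations across the code series lay between −0.63 and −0.38. The check therefore cannot tell which DM22 libraries belong together. The pairing within the DM22 libraries rests on the replicate numbers in the labels alone, not on a stated shared animal, litter or day. Label codes beginning with DM22 (replicates 1 and 2) and DM24 (replicate 3) gave the code series used as a term. What the codes mark was not given in the sources used here.

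Gene lists for 23 pathways and 14 cell types were fixed before the data were examined. They held 681 genes, of which 675 were in the table, 6 of those through an older symbol or synonym. The 32 lists with at least 3 tested genes were tested, and the other 5 were left out. The test was limma's camera with a preset correlation of 0.01 between genes, against all other genes, with Benjamini-Hochberg adjustment over the lists. With an estimated correlation, camera called 0 of the 32 lists in each of the designs without a term, with the block and with the series. Fry, which tests whether a list moves on balance and does not compare it with other genes, was run beside it. Gene names are those of the deposited table, and coordinates (1-based) are from the GENCODE M21 annotation of GRCm38.

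Genes were named by a rule fixed before the data were examined: Yap1, then the 12 genes higher and the 12 lower with the largest log2 difference among those with an adjusted p under 0.05, a mean of at least 50 and no overlap between the groups, without unnamed predicted genes, then up to 4 passing members of each list or else up to 2 with the largest difference as values, and 10 core genes (Wwtr1, Tead1, Gli1, Gli2, Ptch1, Jun, Fos, Fosl1, Ccn1 and Ccn2, the last 2 listed as Cyr61 and Ctgf). Limma called no gene, so after the results were seen the rule was applied to the DESeq2 calls. Members that passed no test were named only for lists called without or with the block.

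The fits were tested on data simulated from the real means of each code series, the library sizes and the dispersions, over 13671 genes in 5 draws with 200 genes of a mean of at least 50 changed in each. Genes of the shifted lists described below were also changed in each draw, and were not counted as unchanged. Limma without a term called 55.4% of genes changed 2-fold, 89.6% of genes changed 4-fold and 96.8% of genes changed 8-fold, and 0.399% of its calls were unchanged genes. DESeq2 without a term called 79.4%, 96.0% and 98.4%, with 3.59% of its calls unchanged genes, and with the series as a term 88.4%, 98.8% and 100%, with 15.4% of its calls unchanged genes. Camera called 100 of 100 lists of 25 genes shifted by −0.33 on the log2 scale and 0 of 100 unchanged lists with either correlation. These simulated genes vary independently within the groups, unlike genes of a real list. In the real libraries limma without a term did not call Yap1 (log2 difference −2.63, adjusted p = 0.517), so the simulated rates may not hold there. Limma's count of 0 calls therefore does not show that few genes changed.

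Alternatives fixed before the data were examined were other pseudocounts (0.5 and 5), no filter or a mean of at least 50, rescaling by median ratios, quantile normalization, limma without trend, without the robust prior or with array weights, the replicate block, the code series as a term, leaving out each library, edgeR and DESeq2, and for lists an estimated correlation, fry, ranks, a mean of at least 50, the block and leaving out each library. Added after seeing the data were edgeR and DESeq2 with the block or the series, DESeq2 without each library, the 4 DM22 libraries alone, and for lists the series as a term, estimated correlations and fry in both designs and 3 other scalings (quantile, median ratios and TMM). The fits without 1 library had no series term, and each held unequal shares of DM22 and DM24 libraries in the groups. A change in such a fit can therefore come from that imbalance. Tables and figures were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.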

Results

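RNA was sequenced from basal cell carcinoma (BCC) cells of mouse ear epidermis. The tumours were driven by SmoM2, a constitutively active form of the Hedgehog signal transducer Smoothened, switched on in Krt14-expressing keratinocytes by tamoxifen given at 4 weeks of age. The cells were taken 6 weeks later. The 6 libraries fell into 2 groups of 3: tumours with wild-type Yap (wild type) and tumours of mice homozygous for a floxed Yap allele with the same Cre driver (knockout). YAP, encoded by Yap1, is the transcriptional co-activator restrained by the Hippo kinases, and it acts through TEAD transcription factors. The study's title names YAP-TEAD signalling and the AP-1 subunit c-JUN. The comparison therefore asked which transcripts differed between the knockout and wild-type tumours, with YAP-TEAD targets, AP-1 subunits and Hedgehog targets as its named groups. Reads assigned to genes numbered 25260431, 22836259 and 15405490 in the wild-type libraries 1 to 3 and 23182921, 25179110 and 15572640 in the knockout libraries 1 to 3. Krt5, a basal keratinocyte keratin, was the most abundant transcript in each of the 6 libraries, at 1.11% to 1.59% of reads.

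Yap1 transcripts were lower in each knockout library than in any wild-type library. Yap1 (chromosome 9, 7931999 to 8004596, minus strand, protein coding, GRCm38) had 5765, 6004 and 5573 normalized counts in wild-type libraries 1 to 3 and 591, 773 and 1764 in knockout libraries 1 to 3. The group means were 5781 ± 216 (SD, n = 3) and 1043 ± 631 (SD, n = 3). The log2 difference was −2.63 with a standard error of 0.39. With limma and Benjamini-Hochberg adjustment over 13671 genes its adjusted p was 0.517, and with DESeq2 it was 1.4e-07. Without knockout library 3, the library with the most residual Yap1, limma gave −3.09 with an adjusted p of 0.0132. The other Yap-family co-activator Wwtr1 (TAZ) had a log2 difference of −0.17 ± 0.19 (SE) and the DNA-binding partner Tead1 one of −0.03 ± 0.13 (SE), neither past the test in limma or DESeq2.

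**Figure D1:**
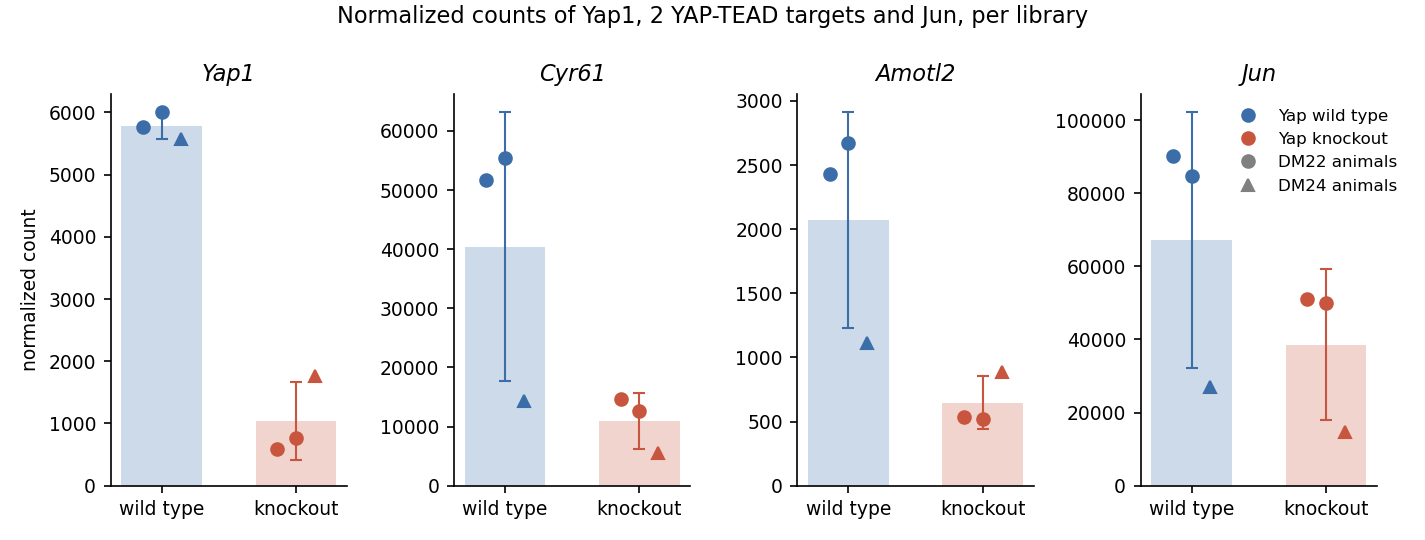
Normalized counts (y axes, linear) of Yap1, Cyr61, Amotl2 and Jun in the wild-type (blue) and knockout (red) libraries; points are libraries, with triangles for replicate 3, bars are group means and error bars the SD (n = 3). Yap1 lies between 591 and 1764 in the knockout libraries and between 5573 and 6004 in the wild-type libraries.

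The transcriptomes also differed along a line that both genotypes shared. Replicates 1 and 2 of each group carried label codes beginning with DM22 and replicate 3 of each group a code beginning with DM24. The X-inactivation transcript Xist had 59594 and 58654 normalized counts in wild-type and knockout library 3 and 8.62 to 15.1 in the other 4 libraries. The Y-linked gene Ddx3y had 3202 to 3426 normalized counts in those 4 libraries and 0 reads in both DM24 libraries, which allows up to 3.90 and 3.79 normalized counts. By these transcripts the DM24 libraries were female and the DM22 libraries male. Depth differed too, with 15405490 and 15572640 reads in the DM24 libraries and 22836259 to 25260431 in the DM22 libraries. Sex, depth and anything else the codes mark therefore cannot be told apart. The first principal component, with 58.0% of the variance, set both DM24 libraries (49.0 and 49.8) apart from the DM22 libraries (−45.3 to −12.0). The second, with 16.7%, set the wild-type libraries (3.79 to 30.9) apart from the knockout libraries (−19.2 to −16.0). With limma and Benjamini-Hochberg adjustment 923 of 13671 genes differed between the code series in a fit that held genotype, so the values within the same-numbered pairs are given beside several named genes and groups. The split of the DM22 libraries into pairs 1 and 2, also used by the block, rests on the replicate numbers alone.

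**Figure D2:**
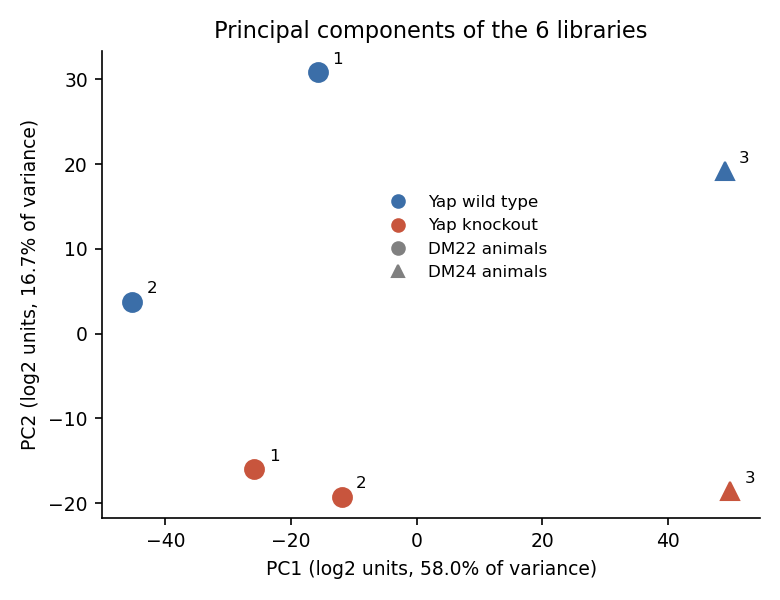
First and second principal components (x and y axes, log2 units) of the 6 libraries, computed from log2 normalized counts of 13671 genes; blue is wild type, red is knockout, circles are DM22 and triangles DM24 libraries, and labels are replicate numbers. The DM24 libraries lie at 49.0 and 49.8 on the first component, and the knockout libraries between −19.2 and −16.0 on the second.

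Among single genes, Amotl2, Epgn, Porcn and Ntn4 were lower and Fat4, Sdk2, Enpp1 and Bmp6 higher in the knockout tumours, by calls that depended on the test. DESeq2 called 67 genes at an adjusted p under 0.05, of which 23 were higher and 44 lower in the knockout. Over all 13671 genes the knockout and wild-type libraries did not overlap for 11.0%, against 10% by chance. Limma, the test fixed before the data were examined, called 0 genes (759 at an unadjusted p under 0.05, with 684 expected by chance), and edgeR called 0 (761 at an unadjusted p under 0.05). With array weights, which ran from 0.288 to 4.91 over the libraries and whose estimation did not converge, limma called 1624 genes, 67 of them DESeq2 calls. In the 4 DM22 libraries alone limma called 2 genes and DESeq2 268. The genes named next therefore come from the DESeq2 calls.

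Among the calls with a mean of at least 50 and no overlap between the groups, the lower genes with the largest log2 differences after Yap1 were Amotl2, an angiomotin family member, Rasl11a, a small GTPase, and Epgn, a ligand of the EGF receptor. Amotl2 (chromosome 9, 102716672 to 102733418, plus strand) had 2073 ± 840 normalized counts in wild type and 647 ± 206 in knockout (SD, n = 3), a log2 difference of −1.62 (DESeq2 adjusted p = 0.00236). Amotl2 did not pass DESeq2 with the replicate block (adjusted p = 0.252) or with the code series as a term (adjusted p = 0.0541), and its differences in the 3 pairs were −2.18, −2.36 and −0.33. Epgn went from 1088 ± 330 to 408 ± 23.8 (SD, n = 3), a log2 difference of −1.37 (DESeq2 adjusted p = 2.3e-05). Porcn, the acyltransferase that Wnt secretion requires, went from 4871 ± 972 to 2075 ± 217 (SD, n = 3), a log2 difference of −1.22 (DESeq2 adjusted p = 3.4e-08). The basement membrane component Ntn4 differed by −1.25 (DESeq2 adjusted p = 2.0e-05), the NF-kB inhibitor Tnfaip3 by −0.91 (DESeq2 adjusted p = 0.000177) and Igfbp7, a secreted growth factor binding protein, by −0.88 (DESeq2 adjusted p = 2.2e-07) on the log2 scale. Rasl11a, Nupr1, Sult5a1, the complement protease C1s and Fam107b completed the 12, with log2 differences of −1.56, −1.02, −0.99, −0.96 and −0.81.

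On the higher side, Fat4, an atypical cadherin, had 217 ± 16.9 normalized counts in wild type and 466 ± 43.1 in knockout (SD, n = 3), a log2 difference of 1.10 (DESeq2 adjusted p = 9.3e-09). Sdk2, a sidekick adhesion molecule, differed by 1.32 (DESeq2 adjusted p = 9.3e-09), the adhesion receptor Bai1 by 2.19 (DESeq2 adjusted p = 0.034) and the neurexin Nrxn2 by 2.05 (DESeq2 adjusted p = 0.0245) on the log2 scale. Enpp1, an ectonucleotidase that makes pyrophosphate, was the most abundant of the 12, at 4938 ± 968 in wild type and 10268 ± 1465 in knockout (SD, n = 3), a log2 difference of 1.07 (DESeq2 adjusted p = 4.9e-05). Bmp6, a bone morphogenetic protein, differed by 1.33, the gap junction gene Gjb6 by 1.13 and the collagen gene Col9a2 by 1.03. Kctd4, Sez6l, Fam101a and Pdlim4 completed the 12, with log2 differences of 1.73, 1.55, 1.08 and 1.05. The number of DESeq2 calls was 169 with the replicate number as a block (57 higher, 112 lower) and 303 with the code series as a term (104 higher, 199 lower), while limma and edgeR called 0 in both designs. Of the 67 genes, 45 were also called with the block and 66 with the series, and of the 24 named by the rule all except Amotl2 passed DESeq2 with the block. In simulated data with the series as a term, 15.4% of the DESeq2 calls were unchanged genes. Leaving out 1 library moved the 67 DESeq2 calls to 23 without wild-type library 1, 223 without wild-type library 2, 235 without wild-type library 3, 26 without knockout library 2 and 233 without knockout library 3. These fits had no series term, and each left the code series uneven between the groups. Of the 24 genes named by the rule, 13 were called without each of the 6 libraries in turn. The other 11, Amotl2, Rasl11a, Sult5a1, C1s, Bai1, Nrxn2, Bmp6, Gjb6, Col9a2, Kctd4 and Fam101a, lost the call without at least 1 library.

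**Figure D3:**
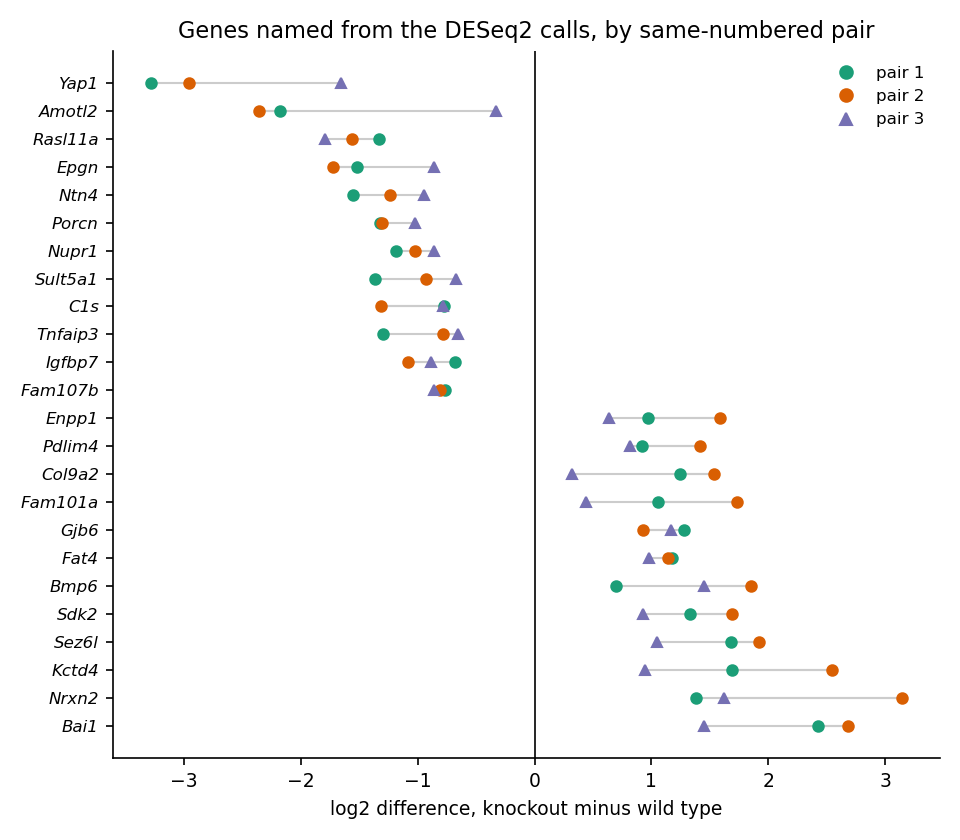
Log2 difference of normalized counts, knockout minus wild type (x axis), in each same-numbered pair for the 24 genes named from the DESeq2 calls (y axis); green, orange and purple are pairs 1, 2 and 3. The rule that named the genes requires groups without overlap and so one direction in the 3 pairs, while the size varies, as for Amotl2, which goes from −2.36 in pair 2 to −0.33 in pair 3.

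Genes known as direct YAP-TEAD targets were lower in the knockout as a group. Of the 20 measured members of that list, 15 had a log2 difference below 0, with a median of −0.24, and the medians of the 3 pairs were −0.24, −0.31 and −0.35. Limma's camera test called the list lower (adjusted p = 0.00113, Benjamini-Hochberg over 32 lists), with an adjusted p = 0.414 with an estimated correlation. By limma 0 members passed over all genes and 0 when adjusted over the list alone, while DESeq2 called 2 members, Amotl2 and Cyr61, both lower, of which Amotl2 did not pass with the block (adjusted p = 0.252) or the series (adjusted p = 0.0541). Cyr61 (Ccn1), a secreted matricellular protein and one of the most used YAP readouts, lies on chromosome 3, 145646976 to 145649981, minus strand. Its mean was 40440 ± 22726 normalized counts in wild type and 10930 ± 4812 in knockout (SD, n = 3), a log2 difference of −1.78 (DESeq2 adjusted p = 0.0381, limma adjusted p = 0.85), with groups that overlapped, and the differences of the 3 pairs were −1.82, −2.13 and −1.38. By limma Cyr61 did not pass with the block (adjusted p = 0.127) or with the series (adjusted p = 0.0681). Cyr61 passed DESeq2 with the block (adjusted p = 3.9e-23) and with the series (adjusted p = 1.7e-28), where the list had 3 and 4 members called lower. Without a term its call held in the fit without wild-type library 3 and was lost without each of the other 5 libraries (adjusted p = 0.24 to 1.0). The related gene Ctgf (Ccn2) had a log2 difference of −0.44 ± 0.58 (SE), within the spread between libraries (DESeq2 adjusted p = 1.0), and its sign turned to 0.11 without knockout library 3. That fit kept the DM24 wild-type library without a DM24 knockout library. The differences of Ctgf in the 3 pairs were −0.89, 0.30 and −0.75. The list of Hippo pathway components, which holds Yap1 itself, was not called (adjusted p = 0.463, median −0.02 over 22 genes). DESeq2 called 2 of its members lower, Yap1 and Wwc2, as did limma when adjusted over the list alone, and Wwc2 had a log2 difference of −0.63 (DESeq2 adjusted p = 0.0294, 0.0766 with the block and 0.0112 with the series). Of the 6 fits without 1 library, DESeq2 called Wwc2 in 2.

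Jun, the gene for c-JUN, had similar differences in the 3 pairs, although its level varied more between the code series than between the genotypes. Jun (chromosome 4, 95049034 to 95052222, minus strand) had 67204 ± 34967 normalized counts in wild type and 38553 ± 20724 in knockout (SD, n = 3). The log2 difference was −0.82 ± 0.66 (SE), and −0.82, −0.76 and −0.88 in pairs 1 to 3. It did not pass limma (adjusted p = 0.987) or DESeq2 (adjusted p = 1.0) without a term, and passed DESeq2 with the replicate block (adjusted p = 6.6e-16) and with the code series as a term (adjusted p = 1.3e-29). Maff, a small MAF family factor, had a log2 difference of −0.96, with −0.97, −0.92 and −0.98 in the 3 pairs (DESeq2 adjusted p = 0.445 without and 1.4e-07 with the block). By limma neither Jun nor Maff passed with the block (adjusted p = 0.213 and 0.123) or with the series (adjusted p = 0.0681 for both). Fos, the classical partner of JUN, had 0.04, −0.33 and −1.56 in the 3 pairs, and Fosl1 had 0.79, 0.55 and −0.65. Over the 17 measured AP-1 subunits, 12 lay below 0 with a median of −0.60. The list was not called by camera without a block (adjusted p = 0.158) and was called lower with the replicate block (adjusted p = 0.00353, and adjusted p = 0.739 with an estimated correlation). Its pair medians were 0.04, −0.24 and −0.86, its direction turned without knockout library 3 (adjusted p = 0.379), and 0 members passed limma over all genes or adjusted over the list alone. The fit without knockout library 3 had no series term and kept the DM24 wild-type library without a DM24 knockout library. The list scores (mean log2 values around the mean of each gene) were 0.35, 0.43 and −0.20 in wild-type libraries 1 to 3. They were 0.23, 0.16 and −0.96 in knockout libraries 1 to 3.

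All 28 members of the list of immediate early and tissue dissociation response genes, which cell stress and tissue handling are known to induce, had log2 differences below 0. Genes of this list vary together (estimated correlation 0.597), so they are not independent. Camera called the list lower (adjusted p = 7.8e-07), with an adjusted p = 0.734 with an estimated correlation. Its median was −0.59, and −0.42, −0.48 and −0.95 in pairs 1 to 3. By limma 0 of its members passed over all genes or adjusted over the list alone, and by DESeq2 0 passed without a term, 11 were lower with the block and 13 with the code series as a term. The chaperone Hspa8 had a log2 difference of −1.37 ± 0.44 (SE) and the MAP kinase phosphatase Dusp5 one of −1.24 ± 0.61 (SE). Both passed DESeq2 with the block (adjusted p = 4.2e-13 and 3.9e-08), and neither passed limma with the block (adjusted p = 0.218 and 0.123). The scores of the list, as mean log2 values around the mean of each gene, were −0.32 in wild-type library 3 and −1.25 in knockout library 3, and 0.11 to 0.62 in the DM22 libraries.

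The Hedgehog targets Gli1 and Ptch1 had high counts in both groups, with Ptch1 means of 19904 in wild type and 14565 in knockout. Other list members had lower means, such as Hhip (1306 and 2051) and Mycn (1988 and 1321). The transcription factor Gli1, a direct Hedgehog target, had 17701 ± 1012 normalized counts in wild type and 17452 ± 3095 in knockout (SD, n = 3), a log2 difference of −0.04 ± 0.15 (SE) that changed sign under quantile normalization (0.03). Gli2 had a log2 difference of −0.18 ± 0.27 (SE). The receptor Ptch1, also a direct target, had one of −0.44 ± 0.23 (SE), which did not pass DESeq2 without a term (adjusted p = 0.849) or with the block (adjusted p = 0.0528) and passed with the code series as a term (adjusted p = 0.00578). Of 21 list members, 18 lay below 0 with a median of −0.16. Camera called the list lower (adjusted p = 0.0104, and 0.734 with an estimated correlation), a call lost without knockout library 3 (adjusted p = 0.578), and the medians of the 3 pairs were −0.14, −0.08 and −0.31. The fit without knockout library 3 kept the DM24 wild-type library without a DM24 knockout library. By limma 0 members passed over all genes or adjusted over the list alone. The members with the largest differences were Hhip (0.82 ± 0.51, SE), a Hedgehog-binding membrane protein, and Mycn (−0.64 ± 0.35, SE), neither past limma. Mycn did not pass DESeq2 without a term (adjusted p = 0.962) or with the code series as a term (adjusted p = 0.163) and passed with the block (adjusted p = 0.00222).

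DNA replication genes were lower in the knockout by a small amount. All 25 members of the S phase list had log2 differences below 0, with a median of −0.33 and pair medians of −0.34, −0.36 and −0.25. Of the 25, 20 did not overlap between the groups, against 11.0% of all genes tested. Genes of this list vary together (estimated correlation 0.125), so they are not independent. Camera called the list lower (adjusted p = 8.9e-25, and adjusted p = 0.131 with an estimated correlation), as did fry (adjusted p = 0.019, without the block). With the block, fry gave an adjusted p of 0.159, and with the code series as a term 0.0363. By limma 0 members passed over all genes and 20 were lower when adjusted over the list alone. DESeq2 called 5 lower, among them the replicative helicase subunit Mcm6, with 4718 ± 280 normalized counts in wild type and 3605 ± 146 in knockout (SD, n = 3), a log2 difference of −0.39 (DESeq2 adjusted p = 0.00282). The licensing factor Cdt1 differed by −0.37, the chromatin remodeller Hells by −0.34 and the sliding clamp Pcna by −0.33 on the log2 scale. With the replicate block DESeq2 called 2 members of the S phase list, Mcm6 (adjusted p = 0.0126) and Rrm2 (adjusted p = 0.0208), and Cdt1 (adjusted p = 0.168), Hells (adjusted p = 0.255) and Pcna (adjusted p = 0.207) did not pass. With the code series as a term DESeq2 called 12 lower, among them Cdt1 (adjusted p = 0.00315), Hells (adjusted p = 0.0139), Pcna (adjusted p = 0.0235) and Rrm2 (adjusted p = 0.00324). Of the 6 fits without 1 library, DESeq2 called Mcm6 in 4, Cdt1 and Pcna in 2 and Hells in 1. Rrm2 and Gins2, with differences of −0.47 and −0.43, did not pass DESeq2 without a term. Of the G2 and M phase list, 26 of 26 members lay below 0 and 3 did not overlap between the groups. Genes of the G2 and M phase list vary together more strongly than those of the S phase list (estimated correlation 0.852). The list had a median of −0.28 and pair medians of −0.47, −0.31 and −0.09. Camera called it lower (adjusted p = 5.3e-11, and 0.734 with an estimated correlation), and 0 members passed limma over all genes or adjusted over the list alone; Ccna2 and Ccnb2, both cyclins, had differences of −0.38 and −0.36.

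**Figure D4:**
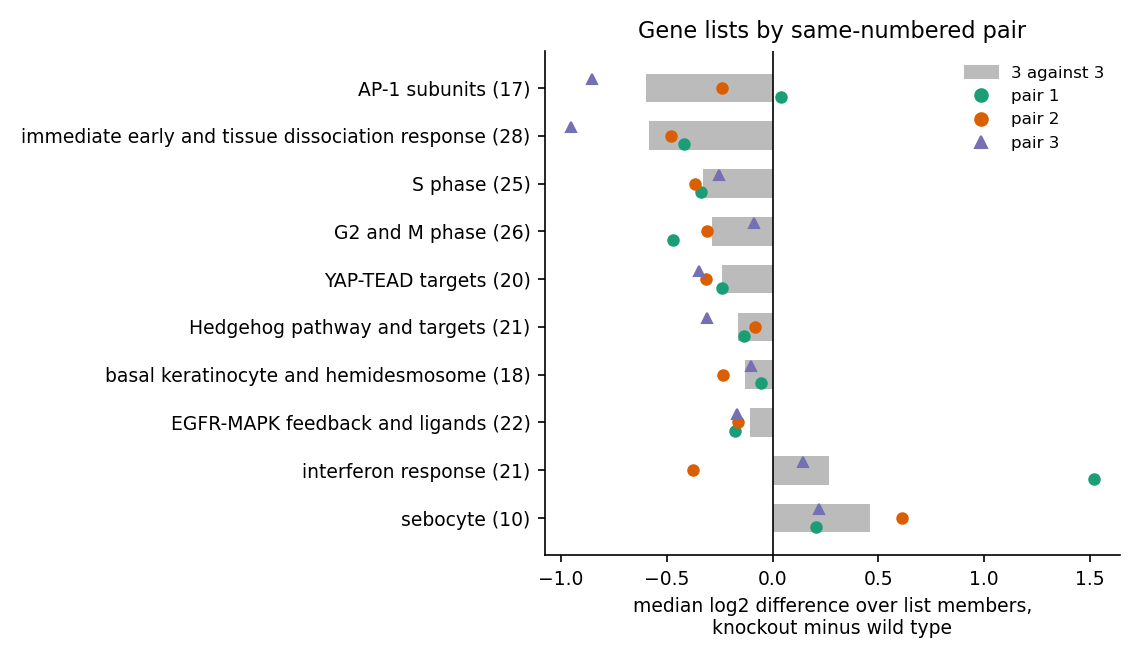
Median log2 difference over list members, knockout minus wild type (x axis), for the lists called by camera without or with the replicate block (y axis, number of genes tested in parentheses); grey bars compare the 3 libraries of each group and coloured points are pairs 1 (green), 2 (orange) and 3 (purple). The S phase list lies between −0.36 and −0.25 in the 3 pairs, and the interferon list between −0.38 and 1.52.

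Genes of the basal keratinocyte and its hemidesmosomes were slightly lower. Of 18 members 14 lay below 0, with a median of −0.13 (camera adjusted p = 0.00558, and adjusted p = 0.524 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.331). The adhesion receptor Bcam had a log2 difference of −0.53, which did not pass DESeq2 without a term (adjusted p = 0.118) and passed with the block (adjusted p = 0.00254) and the series (adjusted p = 4.2e-05), and the integrin subunit Itga2 one of −0.49. By limma 0 members of this list passed over all genes or adjusted over the list alone. The EGFR-MAPK list had a median of −0.11 over 22 genes and was not called without a term (adjusted p = 0.089). It was called lower with the block (adjusted p = 0.0162, and adjusted p = 0.571 with an estimated correlation) and with the code series as a term (adjusted p = 0.0292). Of its members Epgn was lower by DESeq2, and the feedback inhibitor Spry4 had a log2 difference of −1.22 that passed neither limma nor DESeq2. Adjusted over the list alone, limma called Epgn lower and Spred3 higher (log2 difference 0.80, named after its values were seen), and over all genes 0 members passed. The interferon list was called higher (adjusted p = 0.0365, and adjusted p = 0.734 with an estimated correlation), with medians of 1.52, −0.38 and 0.15 in pairs 1 to 3, and the call was lost without knockout library 1, where the direction turned (adjusted p = 0.923). It was not called with the block (adjusted p = 0.121) or with quantile normalization (adjusted p = 0.168). Its members Oas1a and Gbp2 had log2 differences of 1.51 ± 0.45 and 1.44 ± 0.69 (SE), and 0 of 21 passed limma over all genes or adjusted over the list alone. All 10 measured sebocyte markers lay above 0, with a median of 0.46 and pair medians of 0.21, 0.61 and 0.22. That list was not called without the block (adjusted p = 0.158) and was higher with it (adjusted p = 0.00412, and adjusted p = 0.571 with an estimated correlation), its scores ran from −1.22 to −0.07 in the DM22 libraries and were 1.11 and 1.41 in the DM24 libraries, and 0 members passed limma over all genes or adjusted over the list alone. Elovl3 and Awat1, its members with the largest differences, had 1.01 ± 1.66 and 1.47 ± 1.83 (SE).

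The other pathway lists were not called by camera without or with the block. Their adjusted p without the block was 0.463 for the JNK pathway (median 0.04), 0.542 for spinous and granular differentiation (0.19), 0.822 for the activated keratinocyte and wound response (0.01), 0.822 for hair follicle progenitors (0.0030), 0.542 for Wnt-beta-catenin targets (0.08) and 0.427 for the Notch pathway (−0.15). It was 0.533 for TGF-beta and SMAD targets (−0.03), 0.533 for p53 targets and cell death (−0.04), 0.463 for actin cytoskeleton and focal adhesion (−0.04) and 0.463 for chemokines and cytokines (−0.03). It was 0.533 for lipid and sterol synthesis (0.05), 0.699 for glycolysis and hypoxia (−0.04) and 0.56 for the unfolded protein response (−0.04). The wound response list had a mean and median above 0 and a camera direction below, and the glycolysis list a median below 0 and a mean and camera direction above. Markers of other cell types were not called either, with adjusted p of 0.139 for Langerhans and dendritic cells (median 0.28), 0.699 for neutrophils (0.28), 0.56 for fibroblasts (median −0.12, mean 0.05), 0.56 for endothelium (0.22), 0.264 for skeletal muscle (−0.40), 0.822 for melanocytes (−0.09), 0.13 for cartilage (0.21) and 0.533 for Schwann cells and nerve (0.13). Within these lists, adjusted over the list alone, limma gave 0 calls in all except cartilage, where Col9a2 was higher. Too few markers of macrophages (Cd68, Cd14), T cells (Lck, Thy1), mast cells, erythroid cells (Alas2) and adipocytes (Lpl) reached the mean of 10 normalized counts for a test of those lists.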

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

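The tests of this part were chosen after the results were seen, including the tests of a difference between the code series. For library scaling of the S phase genes the bounds were recorded as fixed beforehand, but the scalings of the lists were added after seeing the data.

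The knockout difference was tested for a change between the DM22 libraries and the DM24 pair, with 1 DM24 library per genotype that is assumed to vary like the others. Sex-linked transcripts and depth also differ between the series, so the source of such a change cannot be told apart. Camera with the preset correlation gave a difference for 12 of 32 lists, and for 0 with an estimated correlation. The G2 and M phase list (adjusted p = 2.99e-09) had pair medians of −0.47, −0.31 and −0.09, and the S phase list (adjusted p = 0.02) −0.34, −0.36 and −0.25. The AP-1 list (adjusted p = 5.75e-05) had 0.04, −0.24 and −0.86, the immediate early list (adjusted p = 5.75e-05) −0.42, −0.48 and −0.95, and the Hedgehog list (adjusted p = 0.016) −0.14, −0.08 and −0.31. Lower in the DM24 pair than in both DM22 pairs were also the lists of TGF-beta targets (adjusted p = 0.0122), hair follicle progenitors (adjusted p = 0.0191), Wnt targets (adjusted p = 0.0192), cartilage (adjusted p = 0.02) and melanocytes (adjusted p = 0.0482). Higher there were glycolysis and hypoxia (adjusted p = 0.0122) and skeletal muscle (adjusted p = 0.0423). Among named genes DESeq2 gave a difference for Amotl2 (adjusted p = 7.4e-09), Fos (adjusted p = 2.7e-06) and Yap1 (adjusted p = 0.000734), while limma gave adjusted p of 0.388, 0.867 and 0.867 for them.

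S phase genes were lower in the 3 pairs. The choice of scaling as the cause is argued against, because the list median nearest 0 over quantile normalization, median ratios and TMM was −0.31. These scalings all set the median over all genes near 0 (0.0001 to 0.0037, and −0.0034 in the main fit). An error that they share was therefore not tested. Dilution by cells that do not cycle cannot be told apart from fewer cycling tumour cells, since the basal keratinocyte list was also lower (median −0.13) by less, and the sebocyte list was called higher with the block and not without it. The 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, gave as small a camera p (2.8e-26, against 4.8e-07 for the next). A lower share of replicating cells in the knockout tumours may remain as a hypothesis, which was not tested.

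The immediate early list was lower in the 3 pairs. Each pair lies within 1 code series, so a level difference between the series alone cannot make a difference within a pair. A difference confined to the DM24 pair is argued against for the 7 heat shock members of the list, with a median of −0.65 in the DM22 pair nearest 0. It stays open for the other 21, with medians of −0.18, −0.38 and −1.16 in pairs 1 to 3, and for the AP-1 list, with 0.04, −0.24 and −0.86. The heat shock members met the bound set for handling or dissociation of the tissue, with medians of −0.65, −0.82 and −0.58 in pairs 1 to 3. With all 28 members of the list below 0 they could not stand apart from the rest of it. Handling can therefore not be told apart from an effect of Yap. Handling was not tested as a cause for Jun, Maff or Cyr61 either. The 10 splits are too few for a share under 0.05: 3, the real one included, gave a camera p as small as its 7.3e-08 (smallest other 1.4e-10), the other 2 setting wild-type libraries 1 and 2 with knockout library 1 or 2 against the rest, which puts both DM24 libraries on one side. With the block the list had an adjusted p of 5.9e-18 (0.545 with an estimated correlation).

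DESeq2 called 67 genes where limma and edgeR called 0. Spread between the code series as the whole cause of this gap is argued against, since with the series as a term limma and edgeR still called 0 and DESeq2 303. Apart from the splits given next, no other explanation of the gap was tested. The 10 splits are too few for a share under 0.05: 3 gave at least 67 DESeq2 calls (highest other 1132) and 6 at least 7 called lists (highest other 13), while for limma all 10 reach its count of 0 by construction (highest other 2). The split with 1132 calls sets wild-type libraries 1 and 3 and knockout library 3 against the rest. The other splits with both DM24 libraries on the same side gave 295, 7 and 11 calls, and the cause was not tested. Of the 4 splits that part the 3 pairs, also too few, 1, the real one, reached its 303 DESeq2 calls with the series as a term, and the highest other had 42.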

How the results depend on the processing

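The DESeq2, edgeR and gene list tests with the code series as a term, the tests in the DM22 libraries alone, DESeq2 and edgeR with a block, DESeq2 without 1 library, estimated correlations and fry with a block or the series, and other scalings of the lists were chosen after the results were seen. Over the alternatives run, values of named genes kept direction and side of the threshold in 1355 comparisons, passed the threshold in 312 and turned sign in 31. The main limma fit called 0 genes, so keeping the side meant not passing. Many of these genes were named because DESeq2 called them, so part of this tally follows from that choice. Lists kept both in 531, lost the call in 50, gained it in 19 and turned direction in 37. Counts stayed within 1.5 times in 72 and moved in 41. The cause was not tested for any change below. Fits without 1 library had no series term and held unequal shares of DM22 and DM24 libraries in the groups.

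Limma's count of 0 genes became 1624 with array weights (790 higher, 834 lower), 2 in the DM22 libraries alone (2 lower) and 0 to 1 without 1 library, the 1 being Yap1 without knockout library 3. DESeq2 called 67 (23 higher, 44 lower). With the replicate block it called 169 (57 and 112), with the series 303 (104 and 199), in the DM22 libraries 268 (122 and 146), and without 1 library 23 to 235 (9 to 126 higher, 12 to 151 lower). Limma and edgeR called 0 genes with the replicate block. The log2 difference of Yap1 was −2.91 with array weights, −2.47 with DESeq2, −2.64 with DESeq2 and the block, −2.63 with DESeq2 and the series, −3.12 (limma) and −3.10 (DESeq2) in the DM22 libraries and −3.09 to −2.18 without 1 library.

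The YAP-TEAD list lost its call with an estimated correlation (adjusted p = 0.414), fry (0.25), fry with the block (0.159), and an estimated correlation with the block (0.545) or the series (0.276). Fry with the series called 3 lists lower, YAP-TEAD, S phase and immediate early, each at an adjusted p of 0.0363. The Hedgehog pathway and targets list lost it in the same settings (0.734, 0.746, 0.468, 0.739 and 0.627), with fry and the series (0.368) and in the DM22 libraries (0.276), and ran from 0.00037 to 0.578 without 1 library. The AP-1 subunits list gained a call with the replicate block (0.00353) and the series (0.00405), and ran from 0.00642 to 0.536 without 1 library, turning direction without knockout library 3 (0.379). Of the other lists, 0 were called with an estimated correlation, 1 with fry, 0 with fry and the block, 2 with fry and the series, 0 with an estimated correlation and the block, 0 with one and the series, and 3 with quantile normalization, where the basal keratinocyte (0.331) and interferon (0.168) lists lost their calls. With the block, EGFR-MAPK (0.0162) and sebocyte (0.00412) also gained and interferon (0.121) lost a call, and with the preset correlation no other list call changed.

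The wound response list turned direction with the block (adjusted p = 0.325, 0.739 with an estimated correlation and 0.821 with fry) and the series (0.544, 0.84 and 0.955). Hair follicle progenitors turned with ranks (0.96), Wnt targets with a mean of at least 50 (0.95), and melanocytes with that filter (0.953). In the DM22 libraries TGF-beta targets (0.723), the glycolysis and hypoxia list (0.471), fibroblasts (0.96) and melanocytes (0.492) turned. Other lists that turned direction without at least 1 library had adjusted p from lowest to highest of 0.0131 to 0.73 (wound response), 0.251 to 0.908 (hair follicle), 0.0871 to 0.96 (Wnt), 0.133 to 0.664 (TGF-beta), 0.263 to 0.928 (glycolysis), 0.258 to 0.96 (fibroblast) and 0.464 to 0.979 (melanocyte). It was 0.0552 to 0.536 for spinous differentiation, 0.284 to 0.992 for p53 targets, 0.000495 to 0.923 for the interferon response list, 0.0538 to 0.941 for the chemokines and cytokines list and 0.122 to 0.822 for lipid synthesis. It was 0.169 to 0.941 for the unfolded protein response, 0.536 to 0.908 for neutrophils, 0.306 to 0.945 for endothelium and 0.00178 to 0.992 for the sebocyte list.

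Gli1 turned sign with quantile normalization (0.033), array weights (0.11) and in the DM22 libraries (0.10 with limma, 0.11 with DESeq2), and Tead1 in the DM22 libraries (0.051 and 0.056). Without 1 library, over limma and DESeq2, the log2 differences ran from −0.14 to 0.12 for Gli1, −0.39 to 0.090 for Gli2, −0.15 to 0.10 for Tead1, −0.28 to 0.0045 for Wwtr1 and −0.85 to 0.11 for Ctgf. They ran from −1.0 to 0.081 for Fos, −0.22 to 0.94 for Fosl1, −1.58 to 3.49 for Elovl3 and −0.95 to 6.97 for Awat1. Awat1 had 0 reads in wild-type libraries 1 and 2 and in knockout library 2. Without wild-type library 3 its difference therefore had no wild-type reads behind it. At 15405490 to 25260431 reads per library, limma called 55.4% of simulated 2-fold changes without a term, 82.2% with the block and 83.0% with the series, where 0.399%, 9.28% and 7.32% of its calls were unchanged genes. Smaller changes were simulated only in the shifted lists, and the share of their single genes called was not computed. In the real libraries limma did not call Yap1 without a term, with the block or with the series (adjusted p = 0.517, 0.218 and 0.117). The simulated rates may therefore not hold for the real libraries.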

Other observations

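The test of the DM22 calls in the DM24 pair was chosen after the results were seen.

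A hypothesis was that the code series shared their knockout difference, so that genes called in the DM22 libraries would keep their sign in the DM24 pair, which took no part in those calls. DESeq2 called 267 genes in the 4 DM22 libraries, Yap1 left out, and 191 of them (71.5%) had the same sign in the DM24 pair. This lay between the 60% and 75% set as bounds, so the test did not decide. The other splits of the 4 DM22 libraries gave 0 and 17 calls, and 47.1% of the 17 kept their sign. The median size of the 267 was 0.79 on the log2 scale in the DM22 libraries and 0.22 in the DM24 pair, counted in the direction of the call. Genes picked for a large difference are measured smaller elsewhere, and genes are not independent replicates. Yap1 itself also differed less in the DM24 pair, by −1.66 on the log2 scale, against −3.28 and −2.96 in pairs 1 and 2. Sex-linked transcripts and depth differ between the series too. Which of these made the median smaller in the DM24 pair was not tested.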
